A study of Mus musculus with 2 samples.

How the data were processed

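RNA sequencing libraries were made from brain endothelial cells of C57BL/6 mouse embryos at E14.5, with 1 library per genotype. The labels' protocols give total RNA from a microextraction kit and 2 µg of RNA as library input, and Illumina sequencing. How endothelial cells were separated from other brain cells is not given in the sources used here, nor is poly(A) selection, ribosomal RNA removal, strand or read length. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.0 and the genome mm9, with no role or order.

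The deposited table lists 16644 genes with their symbols, positions and biotypes. Per the file headers and the values, the authors gave whole-number counts per gene for each library, not normalized. The lowest summed count of a listed gene was 2, so genes without reads were left out before deposit. The authors' normalized columns are CPM (counts scaled to a common library total) of totals of 18427923 and 23349268, slightly above the sums of the listed counts, with a count of 0 written as the CPM of 0.5 counts (0.0271 and 0.0214 CPM). The authors' log2 fold change equals the log2 ratio of those CPM columns. The authors' p-value and adjusted p-value columns come from a test whose tool and adjustment are not given in the sources used here. The adjusted p was below the p in 14826 genes and its highest value was 0.109, which an adjustment that only raises p-values would not give. No column of another sample was in the table.

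The positions in the deposited table were set beside GENCODE M21 (GRCm38). Of the 16610 gene identifiers found in both, 89.3% had identical positions and 100% overlapping ones, so coordinates are given as GRCm38, and mm9 was not used.

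Columns were tied to genotypes through the genotype words and the sample numbers in their names. The KO library held 18426286 counts and the WT library 23348584. The 10 highest genes took 4.84% and 5.18% of them and mitochondrial genes 1.45% and 1.84%. A count was worth 0.0539 CPM in the KO library and 0.0432 CPM in the WT library. Genes at 0 in a library were given a floor of 3 counts there (0.162 and 0.129 CPM) and an "at least" ratio against that floor. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

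Libraries were scaled with trimmed mean of M-values factors from edgeR 4.0.16 in R 4.3.3. The log2 ratio of KO to WT used a prior of 2 counts per library, scaled to its size. Folds were ratios of scaled CPM with an exact conditional binomial (Clopper-Pearson) 95% interval. A gene was measured with at least 10 counts in a library. Genes were counted as higher or lower at 2-fold or more, with no test, since with 1 library per genotype no spread between embryos can be estimated. For each gene list the median log2 ratio of the measured members less the median of all measured genes was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression. A median was given for lists with at least 5 measured members. Lists with genes at 0 in a library were also computed with those genes at their bound, and the value is given where the median differed. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, and matplotlib 3.10.9 for figures.

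The lists, the design, the rule for named genes and the main alternatives were written before the data were examined. The 32 fixed lists with 435 genes cover BET proteins and elongation partners, pan-endothelial markers, barrier, tip cell, arterial, venous, Wnt, TGF-beta, proliferation, p53, cell competition, apoptosis, matrix, secreted factor, NF-kB, interferon, hypoxia and glycolysis, mitochondrial, ribosomal, histone, immediate early, unfolded protein response and sex-linked genes, and markers of neural progenitors, neurons, pericytes, fibroblasts, macrophages, erythroid cells, oligodendrocytes and choroid plexus. A further 4 lists (granulocyte and myeloid progenitor, megakaryocyte and platelet, haematopoietic progenitor, lymphocyte) were chosen after the highest genes had been seen. Some genes stand in more than 1 list. Named genes were Brd4, then the 15 highest and the 15 lowest log2 ratios among 8845 measured genes with a mean of at least 10 CPM and no clone-style symbol of the kinds set beforehand, then up to 4 members per list with the largest absolute log2 ratio at that level. List members were also named as examples or exceptions. Biological process terms in the deposited table with 20 to 300 measured genes (844 terms) were ranked by the same median less that of all genes, without matching on expression. Only the 15 highest and the 15 lowest terms were then placed among matched random lists.

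The procedure was tested on simulated counts for the 15686 measured genes at the real means and library sizes, with 200 genes changed 4-fold. Of those, 98.5% passed 2-fold in the true direction, while 0.84% of unchanged genes did so in either direction, and 95.8% of intervals held the true fold. The simulation holds counting noise only. Exon numbers per transcript for genes without introns came from GENCODE M21.

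Alternatives were total counts, DESeq2 1.42.0 size factors and upper quartile scaling, the authors' CPM with a pseudocount of 1, no filter and a filter of 50 counts, priors of 0.5 and 10 counts, a 3-fold threshold, and leaving out other cell types' and mitochondrial genes. Chosen after the data were seen were protein-coding genes only, no X or Y genes, and a mean of at least 10 CPM. Strand-unaware counting cannot separate a gene from an overlapping or antisense partner, and globin, histone, protocadherin and Acot genes have similar copies, so single values in these families are uncertain.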

Results

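Gene expression was measured by RNA sequencing in mouse brain endothelial cells, the cells that line brain blood vessels, taken from embryos at E14.5 on a C57BL/6 background. The 2 libraries came from embryos grouped by whether Brd4 had been knocked out in endothelial cells, with 1 Brd4 KO library and 1 Brd4 WT library. The KO library held 18426286 gene counts and the WT library 23348584, over 16644 listed genes. Of these, 15686 genes had at least 10 counts in a library and are called measured. With 1 library per genotype no difference has a replicate check, so a ratio compares these 2 libraries and not the genotypes. Intervals, floors and "at least" bounds cover counting error only.

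The targeted gene, Brd4, a bromodomain protein that binds acetylated histones and recruits the transcription elongation factor P-TEFb, was 1.14-fold lower in the KO library (95% interval 1.03 to 1.25, log2 ratio -0.18). It had 766 counts in the KO library and 1086 in the WT library over the gene ENSMUSG00000024002, a protein-coding gene on chromosome 17 from 32196274 to 32284722 (GRCm38). The labels do not say which part of the gene was deleted, and reads from exons outside a deleted part would still be counted, so this value is a weak check of the labels. The close relative Brd2 was 1.75-fold higher (1.68 to 1.83), Med1, a subunit of the Mediator complex, was 2.72-fold higher (2.54 to 2.91) and Hexim1, an inhibitor of P-TEFb, was 1.95-fold higher (1.70 to 2.24). Of the 16 measured BET proteins and elongation partners, 2 were at least 2-fold higher and 0 at least 2-fold lower. Their median log2 ratio lay 0.07 above that of all measured genes, at percentile 86.8 of 10000 random lists matched on expression.

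Sex-linked genes also separated the libraries. Xist, the RNA that coats the inactive X chromosome, had 2390 counts in the KO library and 0 in the WT library, at least 995-fold higher. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had 3741, 1331, 763 and 238 counts in the WT library and 0 in the KO library, which put Ddx3y at least 999-fold lower. The median log2 ratio of the 5 sex-linked genes was -8.57 less that of all genes, -7.81 with the genes at 0 set to their bound and -5.18 with the authors' CPM and a pseudocount of 1. By these genes the KO library came from female and the WT library from male cells, so genotype and embryo sex are confounded in every comparison here.

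Across the transcriptome, 4463 measured genes (28.5%) were at least 2-fold higher in the KO library and 2525 (16.1%) at least 2-fold lower. Among the 2361 genes with a mean of 100 CPM or more, 105 were higher and 128 lower. Among the 1793 genes with a mean under 1 CPM, 1151 were higher and 396 lower. In counts simulated at these depths with counting noise only, 0.84% of unchanged genes passed 2-fold in either direction. Spread between embryos and uneven capture of RNA were not simulated. That share therefore does not say how many of the genes past 2-fold differ beyond such spread. The median of all measured genes was a log2 ratio of 0.14, and list medians are given relative to it. With a filter of 50 counts that shift was smaller, and list medians close to 0 moved by over 1.5 times, to 0.16 for BET proteins, -0.043 for tip cell, -0.10 for proliferation, -0.15 for apoptosis, -0.065 for fibroblast and -0.0083 for ribosomal protein genes. The WT library had more genes at 0 (2732) than the KO library (740), although it held 1.27 times as many counts. Of 62 genes of RNA processing, DNA repair and mitochondrial translation at 2 to 10 CPM in the KO library, 8 had 0 counts in the WT library, so a count of 0 there was also seen in genes that most cells use.

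**Figure D1:**
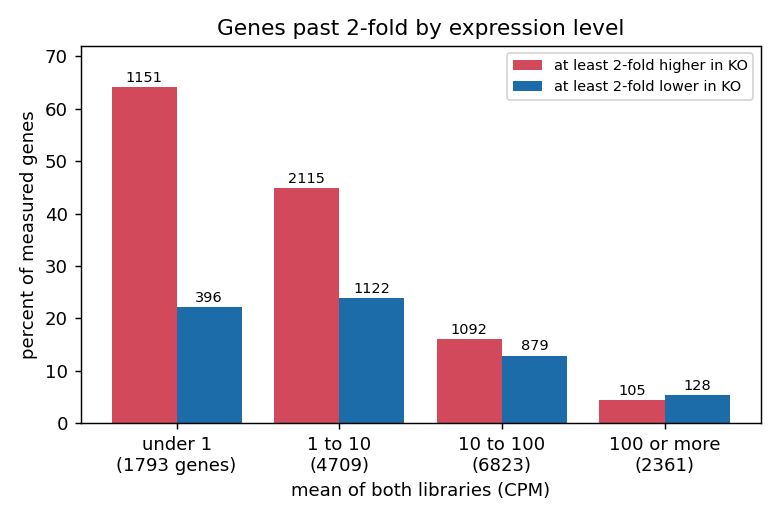
Percent of measured genes at least 2-fold higher (red) or lower (blue) in the KO library, by the mean CPM of both libraries, with the number of genes above each bar. In percent the excess of higher over lower genes is widest under 1 CPM (64.2% against 22.1%), and at 100 CPM or more the lower genes are more numerous (128 against 105).

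The 15 genes with the highest ratios in the KO library all had 0 counts in the WT library. Thbs1, a secreted matrix protein that inhibits angiogenesis and is also stored in platelets (chromosome 2, 118111876 to 118127133), had 5023 counts against 0, at least 2090-fold higher. Prtn3 and Elane, serine proteases of neutrophil granules, had 3499 and 1157 counts against 0, and Serpinb1a, an inhibitor of such proteases, had 1986 against 0. Itgb2, the beta chain of leukocyte integrins, had 1574 counts against 0, Dock2, an activator of Rac in leukocytes, 1350 against 0, and Nfe2, a transcription factor of platelet formation, 1156 against 0. Rgs18 (1622), Rab27b (1536) and F13a1, a subunit of coagulation factor XIII (1434), likewise had 0 counts in the WT library. The remaining genes of the 15 were Xist, the urea transporter gene Slc14a1 (2084), the neuronal microtubule gene Map2 (1602), Atp8b4 (1100) and Fam78a (1076), each at 0 in the WT library.

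At the other end, besides the Y-linked Ddx3y, Eif2s3y and Uty, the lowest ratios belonged to Slc29a4, a plasma membrane monoamine transporter gene (chromosome 5, 142692512 to 142722490), with 0 counts against 1274, at least 340-fold lower, and to Gja5, which encodes the arterial gap junction protein connexin 40 (chromosome 3, 96904693 to 97077416), with 0 counts against 1043, at least 278-fold lower. Igsf5, Stox1, Pcdhb14, AC159633.2 and Acot6 had 757, 755, 728, 532 and 522 counts in the WT library and 0 in the KO library. Slc6a8, the creatine transporter gene on the X chromosome, was 103-fold lower (49.8 to 257), Col6a3, a chain of collagen VI, 68.7-fold lower (33.1 to 172) and Zfp169 136-fold lower (52.9 to 501). Ctse, with 1 count against 484, and Foxl2os, with 19 against 768, were also among the 15. Pcdhb14, Acot6 and Zfp169 belong to families of similar genes among which reads can be split.

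**Figure D2:**
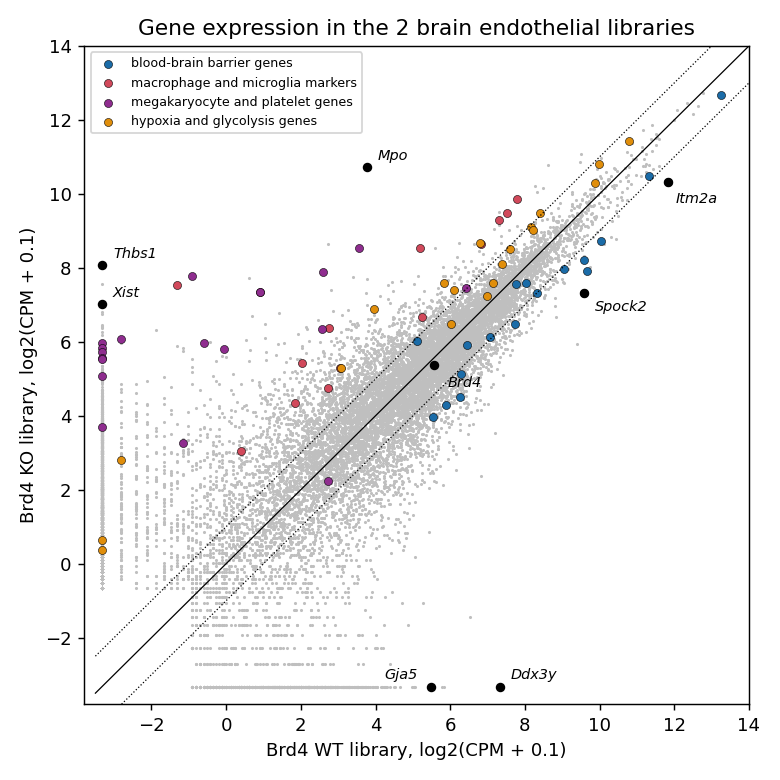
Each point is a measured gene, placed by log2(CPM + 0.1) in the WT library (x axis) and the KO library (y axis), with 4 gene lists in colour and 8 genes named; the solid line marks equal values and the dotted lines 2-fold. Macrophage and megakaryocyte genes lie above the upper dotted line apart from Rasgrp2 (86 counts against 151), most blood-brain barrier genes lie below the solid line, and Brd4 lies near it (41.3 against 46.9 CPM).

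Most genes of endothelial identity had lower values in the KO library. Of the 20 pan-endothelial markers, 18 lay below the median of all genes, 5 were at least 2-fold lower and 0 at least 2-fold higher. Tek, the receptor for angiopoietins, was 2.50-fold lower (2.39 to 2.61), Plvap, a component of fenestral diaphragms, 2.42-fold lower (2.32 to 2.53) and Ramp2, part of the adrenomedullin receptor, 2.26-fold lower (2.16 to 2.37). The abundant receptor gene Kdr was 1.33-fold lower (1.31 to 1.35) and Pecam1 1.34-fold lower (1.31 to 1.37). The list's median was -0.91 less that of all genes, below all 10000 random lists, and the summed CPM of its members was 1.54-fold lower (1.53 to 1.55). In the same library the summed CPM of the 14 macrophage and microglia markers was 4.75-fold higher (4.67 to 4.83).

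Of the blood-brain barrier genes, 18 of 19 lay below the median of all genes, with 11 of 19 measured members at least 2-fold lower and 0 at least 2-fold higher. Spock2, a secreted proteoglycan gene (chromosome 10, 60106219 to 60135198), was 4.87-fold lower (4.69 to 5.07), and Mfsd2a, the lipid transporter gene that limits transcytosis across the barrier, 3.35-fold lower (3.25 to 3.46). Adgra2, a co-receptor for Wnt7 in brain endothelium, was 3.35-fold lower (3.01 to 3.73) and the tight junction gene Ocln 3.04-fold lower (2.71 to 3.43). Cldn5, the main claudin of the barrier, was 1.81-fold lower (1.78 to 1.83) and the glucose transporter gene Slc2a1 1.49-fold lower (1.48 to 1.50), while Slc16a1 was 1.89-fold higher (1.72 to 2.06). The median was -1.30 less that of all genes, below all 10000 random lists.

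Targets and regulators of Wnt/beta-catenin signalling, the pathway that sets up the barrier, had a median of -0.997 less that of all genes (percentile 0.04). Of 17 measured, 7 were at least 2-fold lower and 3 at least 2-fold higher. Nkd1, a feedback inhibitor of the pathway, was 6.47-fold lower (5.77 to 7.29), Apcdd1 4.46-fold lower (4.25 to 4.69), Tnfrsf19 2.39-fold lower (2.30 to 2.48) and the transcription factor gene Lef1 2.26-fold lower (2.15 to 2.37). The relative Nkd2 was 2.38-fold higher (1.98 to 2.87), and Axin2 had 24 counts against 51. Beside this list, the pan-endothelial median in the same library was -0.91, and macrophage and microglia markers summed to 4.75-fold higher.

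Arterial and venous genes went both ways, with more members lower than higher at 2-fold. Among the 15 Notch and arterial genes, 4 were at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.57 less that of all genes (percentile 2.63). Besides Gja5, the Notch ligand gene Jag2 was 3.29-fold lower (3.07 to 3.54) and Gja4, which encodes connexin 37, 2.41-fold lower (2.28 to 2.55), while the Notch ligand gene Dll1 was 2.46-fold higher (2.02 to 3.02). Among the 6 venous genes, 3 were at least 2-fold lower, with a median of -1.09 (percentile 0.09). Slc38a5, an amino acid transporter gene on the X chromosome, was 10.99-fold lower (10.35 to 11.7), Ephb4 3.39-fold lower (3.13 to 3.67) and the apelin receptor gene Aplnr 3.16-fold lower (3.08 to 3.24), while Nr2f2, a transcription factor of venous fate, was 1.30-fold higher (1.21 to 1.39). The pan-endothelial markers had a median of -0.91 less that of all genes in the same library, and the macrophage and microglia markers one of 2.24 above it.

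Within the tip cell and sprouting list, 4 of 15 genes stood apart. Adm, which encodes adrenomedullin, was 4.43-fold higher in the KO library (4.32 to 4.53), Angpt2, an antagonist ligand of Tek, 4.30-fold higher (4.07 to 4.54), Esm1, a marker of tip cells, 3.63-fold higher (3.49 to 3.77) and the chemokine receptor gene Cxcr4 3.61-fold higher (3.0 to 4.37). The other members lay within 2-fold, so that the list's median was -0.13 less that of all genes (percentile 62.1), while its mean log2 ratio of 0.44 lay above the all-gene median. In the same library the pan-endothelial median was -0.91, and macrophage and microglia markers summed to 4.75-fold higher. Which cells the counts of the 4 genes came from was not tested.

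Genes of the hypoxia response and glycolysis were higher together, with all 19 measured members above the median of all genes. Bnip3, a mitophagy receptor induced by hypoxia, was 7.63-fold higher (6.82 to 8.56), hexokinase 2 (Hk2) 4.73-fold higher (4.03 to 5.57), the lactate exporter gene Slc16a3 3.67-fold higher (3.50 to 3.84) and Ankrd37 3.39-fold higher (3.19 to 3.62). The lactate dehydrogenase gene Ldha was 1.76-fold higher (1.73 to 1.79). In all, 9 were at least 2-fold higher and 0 at least 2-fold lower. The median was 0.81 above that of all genes, higher than all 10000 random lists. All 14 macrophage and microglia markers were also at least 2-fold higher in this library, and the libraries do not show which cells the hypoxia and glycolysis counts came from.

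Of 15 basement membrane and matrix genes, 14 lay below the median of all genes, 6 were at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.65 less that of all genes (percentile 0.33). The laminin chain gene Lama5 was 13.6-fold lower (9.30 to 20.7), the collagenase genes Mmp2 3.46-fold lower (2.94 to 4.10) and Mmp14 2.64-fold lower (2.40 to 2.91), and the collagen gene Col18a1 2.77-fold lower (2.70 to 2.83), while the protease inhibitor gene Timp3 was 2.26-fold higher (2.14 to 2.38). The 21 endothelial secreted factors, which include signals known to act on neural stem cells, had 5 members at least 2-fold lower and 7 at least 2-fold higher, and a median of -0.79 less that of all genes (percentile 0.09). Serpinf1, which encodes the neurotrophic factor PEDF, was 5.69-fold lower (4.83 to 6.73) and the semaphorin gene Sema3g 3.76-fold lower (3.38 to 4.2), while Angpt2, also on this list, was 4.30-fold higher and the growth factor binding protein gene Igfbp3 2.02-fold higher (1.91 to 2.14). Members went both ways, with a mean log2 ratio of -0.00021 and a summed CPM 1.58-fold lower (1.56 to 1.60). That mean includes Sema3c (30 counts against 0) and Vegfa (22 against 0), whose positive ratios are set largely by the prior count. Beside these 2 lists the pan-endothelial median was -0.91, with a summed CPM 1.54-fold lower, and macrophage and microglia markers summed to 4.75-fold higher. Among the 13 TGF-beta and BMP response genes, 3 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 0.28 above that of all genes (percentile 97.0) that turned to -0.09 without the filter on low counts. In that list the pseudoreceptor gene Bambi was 2.99-fold lower (2.85 to 3.13), the receptor gene Tgfbr2 1.92-fold lower (1.83 to 2.02), Id2 1.73-fold higher (1.61 to 1.86) and Smad7 1.69-fold higher (1.47 to 1.93).

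The series title names cell competition, the removal of less fit cells by fitter neighbours. Of 13 measured cell competition genes, 1 was at least 2-fold higher (Ripk1, 300 counts against 88) and 1 at least 2-fold lower (Yap1, 2.63-fold, 2.39 to 2.89). The competition driver Myc was 1.50-fold higher (1.42 to 1.58), the polarity gene Llgl1 1.62-fold higher (1.48 to 1.77) and Sparc 1.55-fold lower (1.53 to 1.57). Their median was -0.39 less that of all genes (percentile 12.3). In the same library the pan-endothelial median was -0.91, and macrophage and microglia markers summed to 4.75-fold higher. Which cells the counts of these genes came from was not tested. Proliferation genes differed little, with 24 of 25 within 2-fold and a median of -0.18 (percentile 44.3); cyclin E2 (Ccne2) was 2.19-fold lower (2.05 to 2.35), Foxm1 1.80-fold lower (1.64 to 1.97), E2f1 1.88-fold lower (1.57 to 2.25) and Cdk1 1.63-fold lower (1.50 to 1.77), while Bub1 was 1.55-fold higher (1.48 to 1.63) and Ccnb1 1.52-fold higher (1.46 to 1.58).

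Among 15 targets of p53, 6 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 0.25 above that of all genes (percentile 90.7). The proapoptotic gene Pmaip1 was 17.6-fold higher (14.7 to 21.3), Sesn2 3.33-fold higher (3.04 to 3.66) and the cell cycle inhibitor gene Cdkn1a 2.74-fold higher (2.64 to 2.84), while the proapoptotic gene Bbc3 was 5.45-fold lower (4.28 to 7.03). Of 14 apoptosis genes, 13 lay within 2-fold, with a median of -0.24 (percentile 32.6), and Bid was 7.54-fold higher (6.52 to 8.74). The caspase inhibitor gene Xiap was 1.88-fold lower (1.77 to 2.00) and Bcl2 1.79-fold lower (1.55 to 2.09). Beside these 2 lists, all 14 macrophage and microglia markers were at least 2-fold higher in this library, with a summed CPM 4.75-fold higher.

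Interferon response genes were higher in the KO library, with 11 of 15 at least 2-fold higher, 0 at least 2-fold lower and a median of 1.73 above that of all genes (percentile 99.9). Bst2, which tethers budding viruses, was 4.03-fold higher (3.73 to 4.36), and the RNA sensor genes Ddx58 and Ifih1 were 3.58-fold (3.19 to 4.03) and 3.36-fold (2.88 to 3.93) higher. The transcription factor gene Irf1 had 402 counts against 0, at least 167-fold higher. Of the 15 genes, 6 reached 10 CPM in the WT library and 5 were at 0 there. In the same KO library all 14 macrophage and microglia markers were at least 2-fold higher, with a summed CPM 4.75-fold higher. The 13 NF-kB and adhesion genes went both ways, with 5 at least 2-fold higher, 2 at least 2-fold lower and a median of 0.47 (percentile 92.5), or 0.19 with no filter. Tnfaip3, a feedback inhibitor of NF-kB, was 7.12-fold higher (5.83 to 8.76) and the adhesion gene Vcam1 had 350 counts against 0, whereas Cx3cl1 was 2.49-fold lower (2.24 to 2.77), Csf1 2.06-fold lower (1.77 to 2.40) and Icam1 1.74-fold lower (1.65 to 1.83).

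Of 10 unfolded protein response genes, 4 were at least 2-fold higher, among them the chaperone cofactor gene Dnajb9 at 5.18-fold (4.57 to 5.89), Herpud1 at 2.10-fold (1.96 to 2.26) and Atf4 at 2.03-fold (1.93 to 2.14), and the median was 0.62 above that of all genes (percentile 99.98). Of 17 immediate early and dissociation stress genes, 4 were at least 2-fold higher, with Ier3 at 9.19-fold (8.34 to 10.1), Egr1 at 3.21-fold (3.13 to 3.29) and Zfp36 at 2.82-fold (2.71 to 2.93), and the median was 0.19 (percentile 99.2). In that list Klf2, a gene induced by blood flow, was 1.72-fold lower (1.57 to 1.90) and Klf4 1.51-fold lower (1.41 to 1.63). In both lists 0 genes were at least 2-fold lower. The same KO library had macrophage and microglia markers at a summed CPM 4.75-fold higher.

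All 20 nuclear genes of mitochondrial respiration lay within 2-fold, with a median of -0.35 less that of all genes (percentile 10.04), from Cox5a at 1.79-fold lower (1.55 to 2.07) to Cox7a2 at 1.64-fold higher (1.49 to 1.80). All 10 mitochondrially encoded genes lay within 2-fold and below the all-gene median, with a median of -0.55 (percentile 3.47), and mt-Nd4 was 1.54-fold lower (1.50 to 1.59). Of 32 ribosomal protein genes, 31 lay within 2-fold, with a median of -0.09 (percentile 66.4), and Rps18 was 2.59-fold lower (2.14 to 3.16). Of 10 replication-dependent histone genes, whose RNAs mostly lack poly(A) tails, 8 were at least 2-fold higher, with Hist1h1c at 2.81-fold (2.68 to 2.94). Their median of 2.27 lay at percentile 69.3 of lists of equally low genes, and was 1.13 with the authors' CPM and a pseudocount of 1.

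Markers of other brain cell types did not move alike. All 14 macrophage and microglia markers were at least 2-fold higher in the KO library, with a median of 2.24 above that of all genes, higher than all 10000 random lists. Csf1r, the receptor that macrophages need to survive, was 3.95-fold higher (3.81 to 4.10), the complement gene C1qa 4.23-fold higher (4.10 to 4.36), the lysosomal gene Cd68 12.3-fold higher (10.4 to 14.6) and the pan-leukocyte phosphatase gene Ptprc 612-fold higher (297 to 1523). Of 18 neuron markers, 13 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 1.69 (percentile 99.0), or 1.07 with the authors' CPM and a pseudocount of 1. Besides Map2, Elavl4 was 6.75-fold higher (5.59 to 8.22), Neurod6 2.36-fold higher (2.2 to 2.53) and Tubb3 2.14-fold higher (1.85 to 2.49), while Dcx had 789 counts against 812.

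The 12 neural progenitor markers went both ways, with 4 at least 2-fold higher and 3 at least 2-fold lower. Nes, an intermediate filament gene also active in growing endothelium, was 2.74-fold lower (2.64 to 2.85), Pax6 1.77-fold lower (1.45 to 2.17) and Sox9 1.60-fold higher (1.51 to 1.70). Their median was -0.08 (percentile 34.3), or -0.54 with a filter of 50 counts, while their mean log2 ratio of 0.29 lay above the all-gene median. That mean includes 3 markers at 0 in the WT library and 1 at 0 in the KO library, whose ratios are set largely by the prior count. The summed CPM of the list was 1.73-fold lower (1.69 to 1.78). Of 12 pericyte and smooth muscle markers, 9 lay within 2-fold, with a median of 0.25 (percentile 94.6), among them the abundant Rgs5 at 1.14-fold higher (1.13 to 1.15) and Vtn at 1.54-fold higher (1.50 to 1.58). Of 6 fibroblast and meningeal markers, 4 lay within 2-fold, with a median of -0.15 (percentile 48.2); Foxc1 was 4.09-fold lower (3.40 to 4.95) and Postn 2.11-fold higher (1.86 to 2.40). Only 3 oligodendrocyte lineage markers (Cspg4, 2859 counts against 2537; Mbp, 220 against 0; Plp1, 40 against 0) and 2 choroid plexus markers (Aqp1, 317 against 0; Clic6, 47 against 220) were measured, too few for a median.

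Red blood cell genes did not move together. Of 8 measured erythroid markers, 5 were at least 2-fold higher and 2 at least 2-fold lower, with a median of 4.79 above that of all genes, or 4.27 with the genes at 0 set to their bound. That median depended on how low counts were treated, from 1.91 with the authors' CPM and a pseudocount of 1 to 6.73 with a prior of 0.5 counts. The embryonic globin genes Hbb-y and Hba-x had 400 and 280 counts in the KO library against 0, while Hba-a1 was 2.06-fold lower (1.82 to 2.33) and Hbb-bs had 9 counts against 157. The erythroid and megakaryocyte transcription factor gene Gata1 had 868 counts against 0, at least 361-fold higher.

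**Figure D3:**
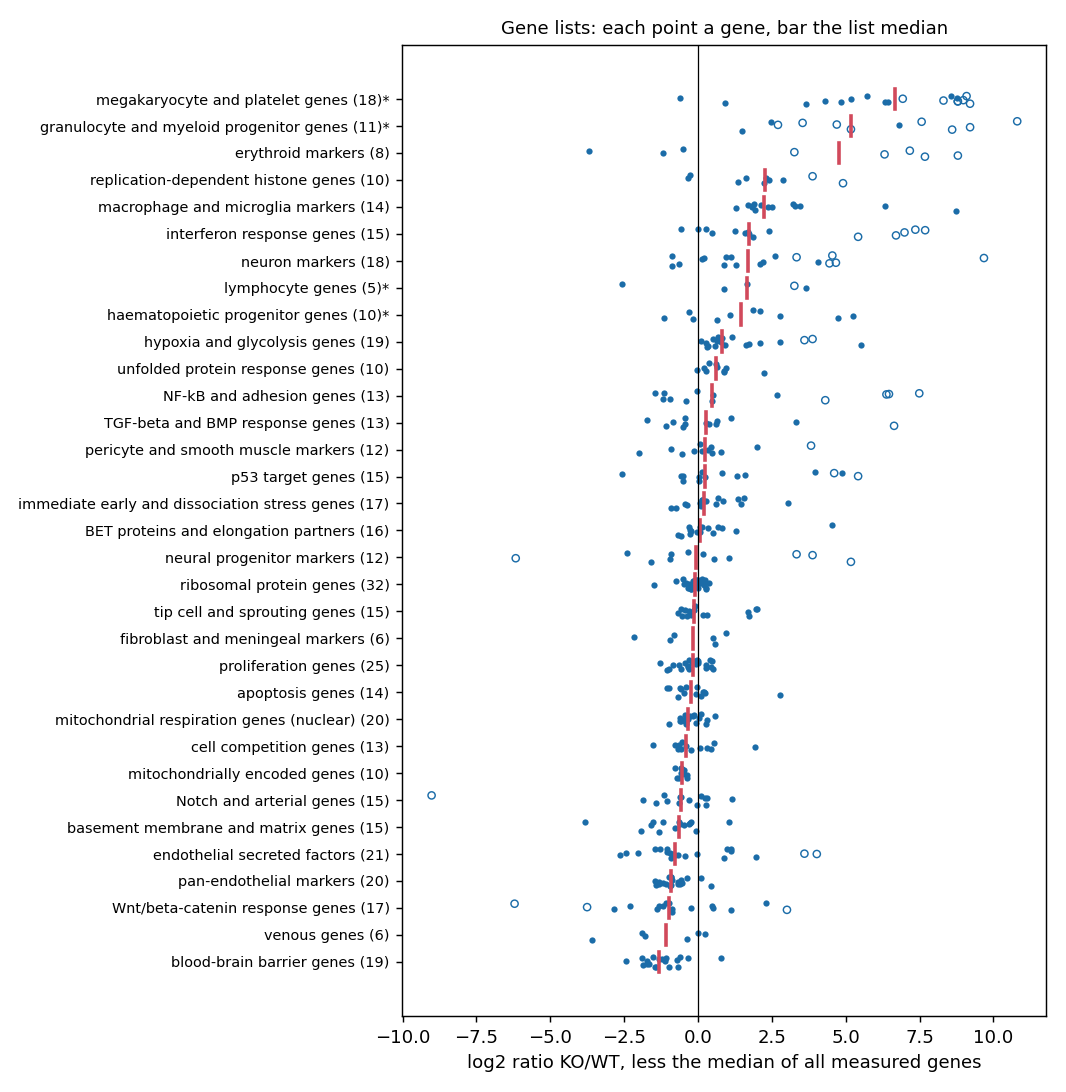
Log2 ratio of KO to WT, less the median of all measured genes, for each measured member (points; open circles have 0 counts in a library) and the median (red bar) of each gene list, with the number of measured members in brackets and lists chosen after the data were seen marked by an asterisk; the sex-linked genes and 2 lists with under 5 measured members are left out. Medians run from -1.30 for blood-brain barrier genes to 2.24 for macrophage markers among lists without an asterisk, apart from the histone genes (2.27) and the erythroid markers (4.79).

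The authors' deposited table called 4935 genes up and 2590 down, 45.2% of the listed genes. Of these, 4459 of the genes called up were also at least 2-fold higher here and 2495 of those called down at least 2-fold lower, and 0 went in opposite directions. Both sets were taken from the same counts with nearly the same scaling, so this overlap is not independent support. The authors' deposited table gave Brd4 a log2 fold change of -0.16 and did not call it. No gene with an absolute log2 fold change under 1.0003 was called, so this follows from size and says nothing about the p-value of Brd4. The authors' p-values compare the reads of 2 libraries, not the genotypes.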

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

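Total counts, DESeq2 size factors and upper quartile scaling moved Brd4 between -0.16 and -0.19 and left every list median within its interval and both counts of genes within 1.5 times. Of 497 named genes besides Brd4, 5 changed sign under some alternative, as did 1 of 34 list medians. The counts moved most with low genes left out: 2948 higher with a filter of 50 counts, 1197 higher and 1007 lower at a mean of at least 10 CPM (chosen after the data were seen), from fewer genes counted, and 1603 lower at 3-fold. The list medians below moved past their counting intervals; the cause was not tested beyond what each setting leaves out or adds. With the authors' CPM and a pseudocount of 1, which pulls low genes toward 0, they were interferon 1.52, mitochondrially encoded -0.49, histone 1.13, neuron 1.07, macrophage 1.98, erythroid 1.91, sex-linked -5.18, granulocyte 2.24, megakaryocyte 5.09 and lymphocyte 0.84. With no filter, TGF-beta changed sign to -0.095, and pan-endothelial was -0.94, NF-kB 0.19, neuron 1.27 and erythroid 2.30. With a filter of 50 counts, which also moved the median of all genes, BET was 0.16, pan-endothelial -0.82, barrier -1.21, tip cell -0.043, arterial -0.48, venous -1.001, Wnt -0.91, TGF-beta 0.37, proliferation -0.10, apoptosis -0.15, matrix -0.56, hypoxia 0.87, mitochondrially encoded -0.46, ribosomal -0.0083, immediate early 0.28, unfolded protein response 0.71, neural progenitor -0.54, fibroblast (within its interval) -0.065, neuron 1.12, erythroid 6.40 and granulocyte 7.28. A prior of 0.5 counts gave erythroid 6.73, sex-linked -10.56, granulocyte 6.83 and megakaryocyte 7.68, and a prior of 10 gave histone 1.54, neuron 1.32, erythroid 2.74, sex-linked -6.256, granulocyte 2.998, megakaryocyte 5.89 and lymphocyte 1.41, as a prior weighs most on low counts. No paired analysis was possible because each genotype had 1 library, and no library could be left out. Depth limits the lowest genes, since 10 counts decide whether a gene is measured.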

Other observations

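Blood cell lineages were covered by 4 lists chosen after the highest genes had been seen. All 11 measured granulocyte and myeloid progenitor genes were at least 2-fold higher, and their summed CPM was 94.8-fold higher (86.8 to 104). Mpo, the myeloperoxidase of neutrophil granules, was the most abundant at 1684 CPM against 13.5, 125-fold higher (112 to 140), and Ctsg had 759 counts against 0. Of 18 megakaryocyte and platelet genes, 17 were at least 2-fold higher, with a summed CPM 14.8-fold higher (14.3 to 15.4). The integrin gene Itga2b was 32.0-fold higher (28.3 to 36.2), Itgb3 508-fold higher (276 to 1061), and Gfi1b and Treml1 had 1065 and 987 counts against 0. The medians of these lists were 5.18 and 6.68 above that of all genes, or 4.71 and 6.46 with genes at 0 set to their bound. Over the alternatives the first ran from 2.24 (authors' CPM with a pseudocount of 1) to 7.28 (filter of 50 counts) and the other from 5.09 (the same CPM) to 7.68 (prior of 0.5 counts). Of 10 haematopoietic progenitor genes, 6 were at least 2-fold higher, 3 within 2-fold and 1 at least 2-fold lower, with a median of 1.47. Runx1, needed for blood formation from endothelium, was 43.1-fold higher (33.3 to 56.8), Vav1 7.50-fold higher (6.83 to 8.25) and Myb 4.06-fold higher (3.35 to 4.95), while the receptor gene Kit was 1.12-fold lower (1.06 to 1.18). Of 5 lymphocyte genes, 4 were at least 2-fold higher (Ighm 3.47-fold, 3.0 to 4.03) and 1 at least 2-fold lower (Lck, 18 counts against 131), with a median of 1.65 at percentile 88.5 of matched random lists, or 0.84 with the authors' CPM and a pseudocount of 1. The 4 globin genes summed to 56.8 CPM in the KO library and 47.3 in the WT library.

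Ranking 844 biological process terms by their medians put phospholipase C-activating receptor signaling (18 of 27 genes at least 2-fold higher, 5 at least 2-fold lower, median 3.02 above that of all genes) and positive regulation of vascular endothelial growth factor production (15 of 23 higher, 2 lower, median 3.02) at the top. Among the next were defense response to bacterium (33 of 52 higher, 3 lower, median 2.62), neutrophil chemotaxis (24 of 40 higher, 4 lower, median 2.01) and cytokine-mediated signaling (43 of 82 higher, 13 lower, median 1.21). The lowest median belonged to embryonic limb morphogenesis (30 genes, 6 higher, 13 lower, median -0.76), and among the next were patterning of blood vessels (30 genes, 6 higher, 6 lower, median -0.71) and insulin receptor signaling (40 genes, 7 higher, 11 lower, median -0.66). This ranking was not matched on expression, and genes with a mean under 1 CPM alone had a median 2.82 above that of all genes. Against matched random lists the 2 top terms lay at percentiles 99.96 and 99.99, and embryonic limb morphogenesis at 0.08. The terms were picked by the same ratios, so these percentiles are no separate support. Of 585 genes with 0 counts in the WT library and at least 100 in the KO library, 14 stood on a blood cell list. The macrophage, erythroid, granulocyte, megakaryocyte, progenitor and lymphocyte lists had only 14, 8, 11, 18, 10 and 5 measured members. The number is thus bounded by list length and does not give the share of the 585 genes that blood cells express.

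For the patterns weighed below, the tests on blood-cell genes not seen before, on protein-coding genes, on genes without introns and on household genes were written before their results; the others were chosen after the results had been seen.

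The blood-cell genes were higher in the KO library while pericyte genes stayed close to the median of all genes. A lower endothelial share that raised every other cell type alike is argued against, since the macrophage median exceeded the pericyte median by 2.00 on the log2 scale (95% bootstrap interval over genes 1.40 to 3.19). Pericytes were the only cell type compared in this way. Neuron markers were also higher (median 1.69, 13 of 18 at least 2-fold higher), while neural progenitor (-0.08) and fibroblast (-0.15) medians were not. A lower endothelial share that raised only some other cell types was not tested. Blood cells or their RNA in the KO library may account for the higher blood-cell genes. Of 26 measured granulocyte, megakaryocyte and progenitor genes whose values had not been looked at, 21 (80.8%) were at least 2-fold higher, against 28.5% of all measured genes. In these 3 lists 8, 7 and 0 measured members had 0 counts in the WT library. Such genes were measured only through the KO library and could only come out higher, so the share does not decide the cause. In the WT library 1, 2 and 6 measured members of these lists reached 10 CPM. The labels name no sort or gate that would remove such cells, and the share of red blood cells was not tested. The 4 globin genes summed to 56.8 CPM in the KO library and 47.3 in the WT library, with members going both ways. Their sum thus did not rise as the granulocyte and megakaryocyte sums did. Genotype or embryo sex as the reason for more blood cells, or for blood genes in endothelium, cannot be told apart from a difference between embryos or dissections with 1 library per genotype.

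More genes were at 0 in the WT library than in the KO library. Shallower sequencing is argued against by a WT to KO ratio of total counts of 1.27. Reads of noncoding genes as the whole cause are argued against by 1.83 times as many protein-coding genes at least 2-fold higher as lower (3325 and 1816). That test counted genes past 2-fold, not genes at 0. Among protein-coding genes with at least 10 counts in the other library, 1487 were at 0 in the WT library and 318 in the KO library. Intronic reads as the whole cause are argued against by protein-coding genes without introns, histone genes left out: of 64 at 0 in 1 library, 51 (79.7%, exact 95% interval 67.8 to 88.7) were at 0 in the WT library, while reads from genomic DNA, which would reach these genes too, were not tested. Fewer distinct RNA molecules in the WT library may add to it: of 62 household genes at 2 to 10 CPM in the KO library, 8 (12.9%) were at 0 in the WT library, where counting error alone would leave none at 0, against 729 of 2522 other protein-coding genes (28.9%), a ratio of 0.446, and in the other direction 1 of 58 (1.72%) and 178 of 2034 (8.75%) were at 0 in the KO library. The ratio of 0.446 lies between the bounds set beforehand for and against, so uneven capture and true absence cannot be told apart at that level.

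Barrier and Wnt response genes were lower in the KO library. A lower share of endothelial RNA may account for some or all of the fall in their pooled median. That median lay -0.24 from that of the pan-endothelial genes, with a 95% bootstrap interval over genes from -0.64 to 0.04. An interval that includes 0 does not show equal falls, and the 2 lists were not tested apart. Summed CPM was 1.86-fold lower (1.85 to 1.87) for barrier genes and 2.21-fold lower (2.18 to 2.25) for Wnt response genes, against 1.54-fold for pan-endothelial genes. A lower share acting alone would lower sprouting genes by as much. Their median lay 0.78 above that of the pan-endothelial genes (0.38 to 2.36), so a lower share alone does not account for their values. This does not argue against a lower share as such, since whether other cells added counts to sprouting genes was not tested. Genotype or embryo sex stays open and untested for both groups of genes, since 1 library per genotype cannot be told apart from 1 embryo pool, sex or dissection.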
